A study of Mus musculus with 24 samples.

How the data were processed

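Skeletal muscle and heart of male C57BL/6J mice were profiled by RNA sequencing in 3 groups of 4 libraries per tissue: control (sham surgery), KPC (cells of the pancreatic cancer line KPC32908, vehicle) and KPC+GnP (the same cells, gemcitabine and nab-paclitaxel). Per the labels' protocols, total RNA was isolated with a miRNeasy kit, 100 ng went into libraries with the KAPA mRNA Hyperprep kit, and these were sequenced as paired ends of 100 bases on a NovaSeq 6000. Groups were taken from the labels. The labels of the control samples also carry the name of the cell line, although the series describes them as sham mice, and they were used here as controls. The number in each sample's title was read as the number of the animal.

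Per the submitters' processing notes, FastQC 0.11.5, STAR 2.5, featureCounts of Subread 1.5.1, edgeR 3.12.1 and the mouse genome mm10 were used. The role of each tool, the annotation and the use of strand in counting are not given in the sources used here. The authors deposited, for each tissue, a table of raw counts per gene and a table of log2 FPKM. Per the file headers, the counts carry gene symbols and 1 column per library. 1 muscle count column, of animal 141, has a name that differs by a final digit from the sample's title and was assigned to it, since no other column carried that animal's number. Checked on 6182 muscle and 6623 heart genes with at least 200 counts in every library, the deposited log2 FPKM differed from log2 counts by a constant per gene and library, with a spread of at most 0.00159 in muscle and 0.00143 in heart. The library part of that constant lay within 0.0719 (muscle) and 0.0259 (heart) of scaling by trimmed mean of M values (TMM), and up to 0.246 and 0.200 from scaling by library totals. Each table lists 14537 genes, of which 14016 symbols matched the gene table and 13993 had 1 locus in the annotation GENCODE vM21 of GRCm38, from which locations were taken. No pair of libraries within a group was a copy, the smallest chi-square per gene between 2 libraries being 14.8.

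Each tissue's counts were fitted in edgeR 4.0.16 under R 4.3.3 with all 3 groups in one model. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total count 15), which left 12760 genes in muscle and 13846 in heart. Libraries were scaled by TMM, and groups were compared with the quasi-likelihood F test and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05 with no fold minimum. In the text, edgeR adjusted p means this test, fold changes come from the fit, CPM are scaled by TMM, log2 CPM carry a prior count of 2, and the groups of a gene do not overlap where all 4 libraries of one lie above all 4 of the other. The difference between tissues was tested in one fit of all 24 libraries with 6 groups, over 14509 genes. Adjusted p-values of gene lists come from camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of one comparison with at least 5 measured members, beside camera with an estimated correlation and fry, and as counts past the threshold over all genes and adjusted over the list alone. The comparisons, the tests, the rule for naming genes and 38 gene lists were fixed before the data were examined.

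Genes were named by a rule. Per comparison, they were the 8 highest and 8 lowest log2 fold changes among genes past the threshold with non-overlapping groups and a mean of at least 2 CPM in the higher group (5 and 5 for KPC+GnP vs control), leaving out unnamed gene models. Added to these were the 3 members of each list described with the smallest p, and, whatever their result, Fbxo32, Trim63, Mstn, Igf1, Pdk4, Cdkn1a, Serpina3n and Lcn2 in both tissues and Nppa, Nppb, Myh6 and Myh7 in heart. For differences between tissues they were the 5 highest and 5 lowest past the threshold, whether or not the groups overlapped. These genes had a mean of at least 2 CPM in the higher group of each tissue. Of the genes so chosen the text gives a part, and some results are not reported here. Gdf15 and the mitochondrially encoded genes were not analysed here. Genes with near-identical relatives, such as Serpina3n, Mt1 and Mt2, Acot1 and the ribosomal protein genes, carry the uncertainty of how shared reads were counted, as do genes that overlap on opposite strands.

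Depth per library was 18285396 to 27382432 counts in muscle and 11020931 to 20969551 in heart. The 10 most abundant genes took 22.1 to 33.4% of counts in muscle and 10.5 to 24.7% in heart. The interval for a ratio with few counts is a 95% Clopper-Pearson interval of the counts and covers counting error alone. The edgeR fit was tested on 5 simulated sets per comparison drawn from these libraries' means and spread. Each set held 100 changed genes per fold size, 500 over the sets. In muscle the fit recovered 54.0% of 2-fold changes for KPC vs control, 52.0% for KPC+GnP vs KPC and 53.4% for KPC+GnP vs control (means of 12673 genes tested). In heart it recovered 47.0%, 43.4% and 43.2% (13747 or 13748 genes), and 16.4% and 18.8% for the 2 differences between tissues (14390 and 14392 genes). Of 1.5-fold changes it recovered 7.00 to 11.2% within a tissue and 0.800 and 1.80% between tissues.

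Alternatives tried for each comparison were size factors by relative log expression (RLE), no filter on low counts, a stricter filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-trend on the deposited log2 FPKM, a fit of only the 2 groups compared, robust estimation of the spread, and leaving out each library in turn. For the difference between tissues they included the animal as a block. Samples with the same number in their titles were taken as the same animal, which pairs 8 muscle with 8 heart libraries. Over 12390 genes, the deviations from the group means of these 8 pairs had a mean r of 0.0511 (−0.281 to 0.281, over 0.1 in 4 pairs), against −0.0107 for 40 pairs of other animals in the same group. Chosen after seeing the data were scaling by library totals alone, the atrial score and the adipocyte score as covariates, fits of only the heart libraries with low or with high atrial transcripts (Myl7 below or above 5 log2 CPM), and fits between tissues of only the 8 animals without the block and of voom without the block. Comparisons that share a group were set beside 100 simulated sets of unchanged groups and beside 6 splits of the shared libraries into separate pairs. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.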

Results

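RNA was sequenced from the skeletal muscle and heart of male C57BL/6J mice to ask what pancreatic cancer, and its treatment with gemcitabine and nab-paclitaxel, change in these tissues during cachexia, the wasting that accompanies the disease. Control mice had sham surgery. KPC mice had cells of the mouse pancreatic cancer line KPC32908 implanted orthotopically, that is, in the organ the line came from, and were given vehicle. KPC+GnP mice carried the same cells and were treated with gemcitabine, a nucleoside analogue, and nab-paclitaxel, an albumin-bound drug that stabilises microtubules. Each of the 3 groups had 4 libraries per tissue, which makes 24 libraries from 16 animals, and 8 animals gave both tissues. Total counts per library were 18285396 to 27382432 in muscle and 11020931 to 20969551 in heart. In muscle the means were 21840650 ± 3035178 (SD, n = 4) in controls, 26694897 ± 564214 in KPC mice and 20083162 ± 1486740 in KPC+GnP mice. In heart they were 16673536 ± 2354598, 16482622 ± 3262178 and 14834324 ± 3000341. The control mice are labelled as untreated, so a comparison of KPC with control covers both the tumour and the vehicle.

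The comparison of KPC with control muscle asked what the tumour changes in muscle. Fbxo32 and Trim63, which encode ubiquitin ligases that mark muscle proteins for breakdown, rose in KPC muscle. Fbxo32 (chromosome 15, 58175879 to 58214932, GRCm38) rose 9.31-fold, from 602 ± 198 CPM (counts scaled to a common library size; mean ± SD, n = 4) to 5603 ± 2842 CPM, a log2 fold change of 3.22 (SE 0.43, edgeR adjusted p = 0.000367). Trim63 (chromosome 4, 134315120 to 134329629) rose 15.1-fold, from 227 ± 51.6 to 3431 ± 2055 CPM, a log2 fold change of 3.92 (SE 0.52, edgeR adjusted p = 0.000367). All 31 measured proteasome subunits rose, by a median log2 fold change of 1.17, with Psmd4 at 1.77 (SE 0.25) and Psma7 at 1.72 (SE 0.25). Of 24 autophagy and lysosome genes, 18 rose and 1 fell, and Tfeb, a transcription factor that drives lysosome genes, rose by 1.04 (SE 0.12, edgeR adjusted p = 0.000307). Of 16 ubiquitin ligases linked to atrophy, 10 rose and 1 fell. Mstn, a secreted inhibitor of muscle growth, rose 2.59-fold to 299 ± 117 CPM from 115 ± 26.03 CPM, and Igf1, a growth factor, fell to 15.4 ± 3.55 CPM from 34.9 ± 8.70 CPM (log2 fold change −1.18, SE 0.21, edgeR adjusted p = 0.00103). For each gene named in this paragraph, the 4 KPC libraries lay entirely on one side of the 4 control libraries.

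**Figure D1:**
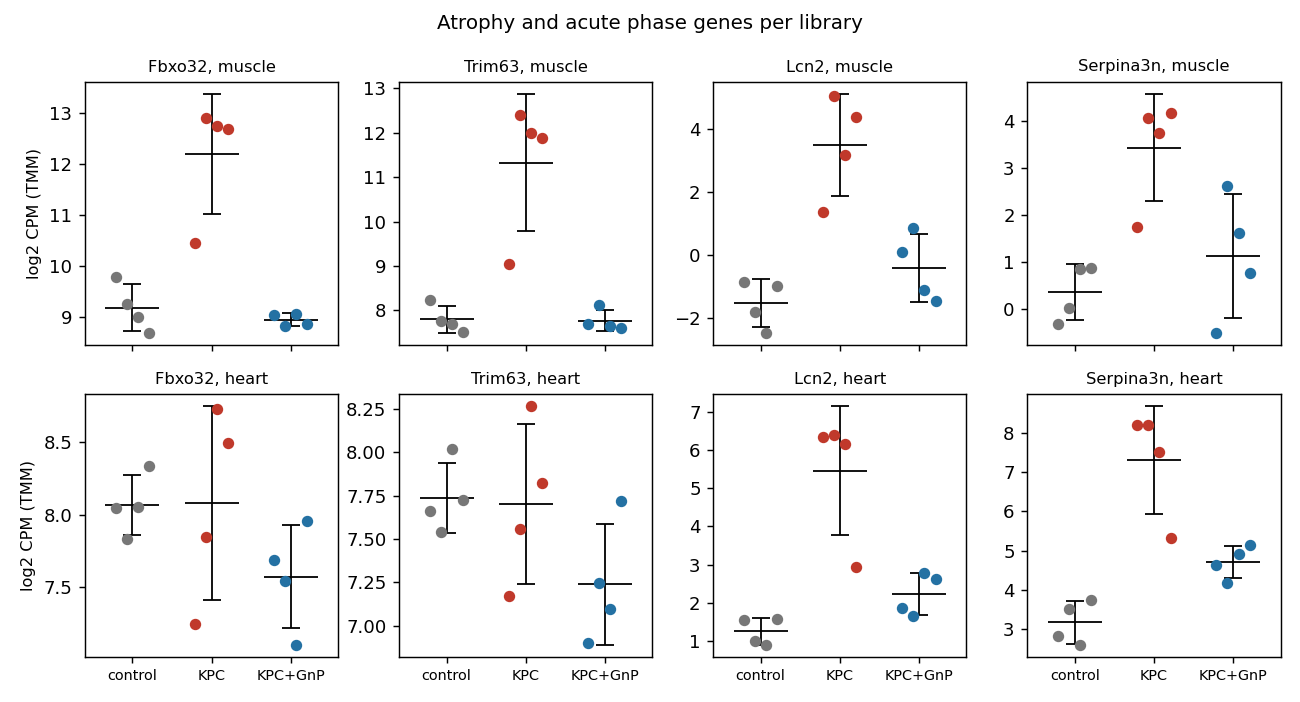
Log2 CPM of Fbxo32, Trim63, Lcn2 and Serpina3n in each library of muscle and heart, with the mean and SD of the 4 libraries of each group. Fbxo32 and Trim63 were higher in every KPC muscle library than in any control or KPC+GnP muscle library, while in heart their groups overlapped.

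Genes induced by glucocorticoids and by interleukin-6 rose alongside. Of 18 glucocorticoid-responsive genes, 16 rose, by a list median of 1.98. Ddit4, an inhibitor of the growth kinase complex mTORC1, rose from 6.33 ± 2.40 to 227 ± 121 CPM (log2 fold change 5.16, SE 0.61, edgeR adjusted p = 0.000307). Cebpd, a stress-induced transcription factor, rose by 4.60 (SE 0.50), Foxo1, a transcription factor that activates atrophy genes, by 3.24 (SE 0.38), and Mt2, a metal-binding protein, by 6.31 (SE 1.15). Pdk4, which blocks entry of pyruvate into mitochondrial oxidation, rose by 2.77 (SE 0.38), to 4164 from 611 CPM. Of 16 interleukin-6 and STAT3 acute phase genes, 9 rose and 0 fell, led in significance by Lrg1 at 1.83 (SE 0.17, edgeR adjusted p = 0.000216). Il6ra, the interleukin-6 receptor subunit, rose by 4.70 (SE 0.63), and Lcn2, an iron-sequestering acute phase protein, rose 55.0-fold to 16.3 ± 13.5 CPM from 0.289 ± 0.176 CPM (log2 fold change 5.78, SE 0.85, edgeR adjusted p = 0.000453). Serpina3n, a secreted protease inhibitor, rose by 3.32 (SE 0.64), and Cdkn1a, which encodes the cell cycle inhibitor p21, by 3.46 (SE 0.60). The largest rise among the named genes was that of Doc2b, a calcium sensor of vesicle fusion, at 7.40 (SE 1.05, edgeR adjusted p = 0.000416). Eif4ebp1, a repressor of translation, rose by 3.48 (SE 0.45), and 36 of 45 cytosolic ribosomal protein genes rose by a list median of 0.41, Rpl4 among them at 0.66 (SE 0.09). Without KPC 2 the rises were 6.21 for Doc2b, 5.38 for Mt2, 5.18 for Lcn2, 4.11 for Il6ra and 2.64 for Cdkn1a.

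Matrix, stromal, interferon and respiratory chain genes fell in KPC muscle. Of 24 extracellular matrix genes, 22 fell, by a list median of −2.55. Col1a1 and Col3a1, the fibrillar collagen chains, fell to 8.89 ± 8.35 from 201 ± 159 CPM (log2 fold change −4.50, SE 0.69, edgeR adjusted p = 0.000551) and to 14.6 ± 13.1 from 366 ± 292 CPM (−4.65, SE 0.74, edgeR adjusted p = 0.000646). Fbn1, a microfibril protein, fell by 3.02 on the log2 scale (SE 0.43). Of 10 fibroblast markers 9 fell, with Lum at −2.50 (SE 0.40), and of 8 smooth muscle and pericyte markers 7 fell, with Acta2 at −1.34 (SE 0.15, edgeR adjusted p = 0.000307). Of 23 interferon response genes 19 fell, by a list median of −1.05, with the interferon-induced GTPase gene Gbp3 at −2.17 (SE 0.35) and the signal transducer gene Stat2 at −1.20 (SE 0.21). Of 43 nuclear-encoded oxidative phosphorylation subunits 31 fell, by a list median of −0.53, with the complex I subunit gene Ndufs1 at −0.77 (SE 0.16, edgeR adjusted p = 0.00202). Without KPC 1 Col1a1 was at −5.37, Col3a1 at −5.46 and Lum at −3.15, and without control 3 Col1a1 was at −3.80 and Col3a1 at −3.99. For every gene named in this paragraph the 4 KPC libraries lay below the 4 controls.

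In all, the edgeR quasi-likelihood test called 6336 of 12760 genes (49.7%) at a Benjamini-Hochberg adjusted p under 0.05, 3512 higher and 2824 lower in KPC muscle, with 995 and 1373 of them changed at least 2-fold. Non-overlapping groups were seen for 4742 genes (37.2%), against 2.86% by chance. Adjusted over the list alone, the counts were 11 up and 1 down for the ubiquitin ligases, 16 for the glucocorticoid genes, 9 for the interleukin-6 genes, 19 for the interferon genes, 33 for the respiratory chain, 23 for the matrix, 38 for the ribosomal proteins, 9 for the fibroblast markers and 7 for the smooth muscle markers. Camera, which compares a list with all other genes at a preset correlation, gave adjusted p = 3.02e-14 for the proteasome, 4.22e-12 for the matrix, 1.45e-11 for glucocorticoid genes, 2.42e-08 for interferon genes, 7.79e-06 for autophagy, 1.64e-05 for fibroblast markers, 0.000509 for interleukin-6 genes, 0.000623 for smooth muscle markers and 0.0123 for the ligases, each at adjusted p = 0.464 with an estimated correlation. Its adjusted p was 1.1e-06 for the respiratory chain (0.826 with an estimated correlation) and 1.3e-07 for the ribosomal proteins (0.523 with an estimated correlation). None of the camera calls in any of the 6 comparisons within a tissue held with an estimated correlation. Fry, which asks only whether the members of a list move on balance one way, gave adjusted p = 0.00392 for the proteasome and 0.00168 for glucocorticoid genes. With scaling by library totals alone the median log2 fold change of all genes was −0.17 instead of −0.00263, and the calls then numbered 6372, of which 2308 were higher and 4064 lower; the lists named above kept their direction.

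The comparison of KPC+GnP with KPC muscle asked whether treatment changes muscle expression in mice with the tumour. Fbxo32 fell to 494 ± 42.0 CPM, 11.3-fold below KPC muscle (log2 fold change −3.50, SE 0.43, edgeR adjusted p = 0.000349), and Trim63 fell to 220 ± 38.3 CPM, 15.6-fold below it (−3.96, SE 0.52, edgeR adjusted p = 0.000356). All 31 proteasome subunits fell, by a list median of −1.22, as did 18 of 24 autophagy and lysosome genes while 1 rose, with Tfeb at −1.17 (SE 0.12, edgeR adjusted p = 0.000321). Doc2b fell to 0.723 ± 0.748 from 40.8 ± 47.2 CPM (−5.78, SE 0.92), Ddit4 to 9.19 ± 5.60 CPM (−4.62, SE 0.59, edgeR adjusted p = 0.000350) and Lcn2 to 0.830 ± 0.662 CPM (−4.28, SE 0.74, edgeR adjusted p = 0.000913). Pdk4 fell by 3.20 on the log2 scale (SE 0.38), Cdkn1a by 3.08 (SE 0.59), Cebpd by 4.10 (SE 0.49) and Il6ra by 4.16 (SE 0.61). Igf1 rose to 36.1 ± 6.98 CPM (1.23, SE 0.21, edgeR adjusted p = 0.000845). The 4 KPC+GnP libraries lay entirely on one side of the 4 KPC libraries for all of these genes. Mstn at −1.25 (SE 0.33, edgeR adjusted p = 0.00803) and Serpina3n at −2.18 (SE 0.59, edgeR adjusted p = 0.00949) also fell, although their groups overlapped. Without KPC 2 Doc2b was at −4.58, Lcn2 at −3.68, Il6ra at −3.57 and Cdkn1a at −2.26, and without KPC+GnP 2 Doc2b was at −6.85, Lcn2 at −4.94 and Serpina3n at −2.88.

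Matrix and interferon genes were higher with treatment. Of 24 extracellular matrix genes 20 rose, by a list median of 2.15, with Col3a1 at 3.67 (SE 0.71, edgeR adjusted p = 0.00151), Col1a1 at 3.37 (SE 0.66, edgeR adjusted p = 0.00164) and Fbn1 at 2.70 (SE 0.42). Kera, a proteoglycan gene of tendon and cornea, rose by 4.19 (SE 0.82). Without KPC muscle library 1 the rises were 7.67 for Kera, 4.48 for Col3a1, 4.23 for Col1a1 and 2.99 for Lum. Of 23 interferon response genes 22 rose, by a list median of 1.20, with Stat2 at 1.43 (SE 0.21, edgeR adjusted p = 0.000467) and the antiviral gene Oasl2 at 1.88 (SE 0.28). Of 10 fibroblast markers 9 rose, with Lum at 2.36 (SE 0.40), and 7 of 8 smooth muscle and pericyte markers rose, with Acta2 at 1.43 (SE 0.15, edgeR adjusted p = 0.000342). Of 43 respiratory chain genes 18 rose, with Ndufs1 at 0.87 (SE 0.16, edgeR adjusted p = 0.00107). Of 12 macrophage markers 7 rose, with the growth factor receptor gene Csf1r at 1.18 (SE 0.24, edgeR adjusted p = 0.00181). Lower in treated mice were 15 of 18 glucocorticoid-responsive genes while 1 was higher, 7 of 16 interleukin-6 genes, and 40 of 45 ribosomal protein genes, with Rpl22 at −0.81 (SE 0.10, edgeR adjusted p = 0.000349).

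**Figure D2:**
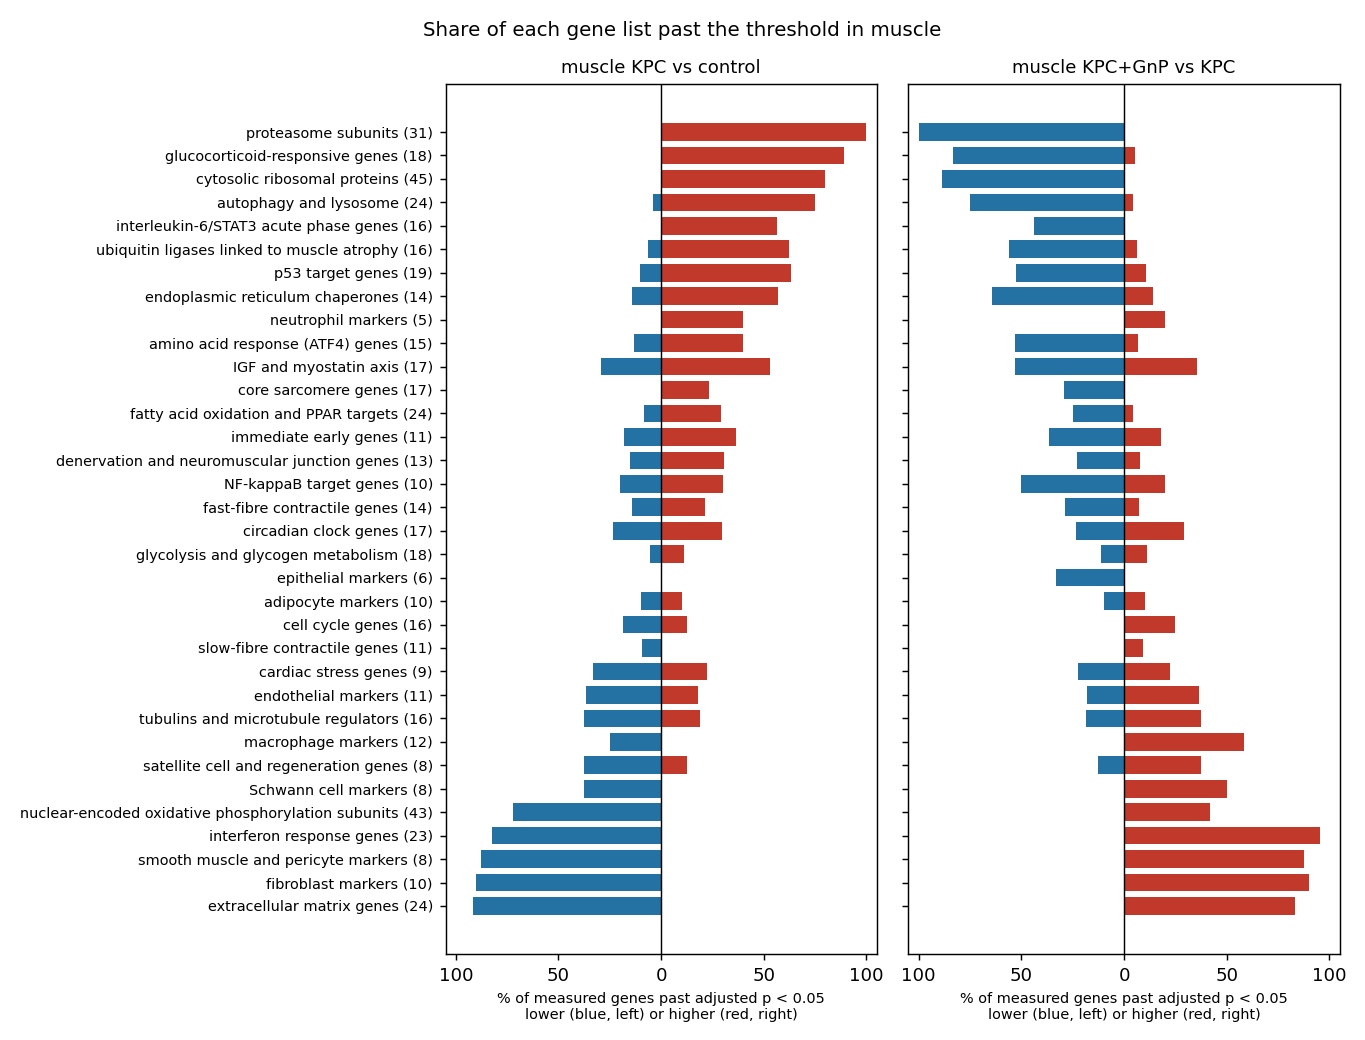
Share of each gene list past the threshold in muscle, in percent, higher to the right and lower to the left, for KPC vs control and for KPC+GnP vs KPC. All 31 proteasome subunits were higher in the first comparison and lower in the second, and the extracellular matrix and interferon lists moved the opposite way.

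EdgeR called 6357 of 12760 genes (49.8%), 2945 higher and 3412 lower with treatment, and 1467 and 915 of them by at least 2-fold. The groups did not overlap for 4289 genes (33.6%, 2.86% by chance). Of the 3512 genes higher in KPC than in control muscle, 3067 (87.3%) were lower with treatment, where 939 are expected of independent lists, and of the 2824 lower genes 2379 (84.2%) were higher, where 652 are expected. By edgeR, 0 genes changed in the same direction in both comparisons. The KPC libraries enter both comparisons with opposite signs, so across genes the covariance of the log2 fold changes was −0.73 (r = −0.955), against −0.0404 in simulated unchanged groups and −0.691 (−0.720 to −0.653 over 6 splits) when each comparison used a separate pair of KPC libraries. Genes are not independent replicates. Adjusted over the list alone, the counts were 21 for the matrix, 22 for interferon genes, 17 for the respiratory chain, 42 for ribosomal proteins, 7 for macrophage markers and 16 down with 1 up for glucocorticoid genes. Camera adjusted p was 3.25e-17 for the proteasome, 3.69e-09 for the matrix, 5.65e-09 for interferon genes, 1.2e-08 for glucocorticoid genes and 4.76e-12 for ribosomal proteins, each at adjusted p = 0.408 with an estimated correlation. It was 0.000172 for the respiratory chain and 0.0265 for macrophage markers, both at adjusted p = 0.783 with an estimated correlation. With library totals alone the median of all genes was 0.27 instead of 0.02, and 6678 genes were called, 4898 higher and 1780 lower.

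The comparison of KPC+GnP with control muscle asked whether treated mice with the tumour still differ from sham mice. Of the 8 genes named whatever their result, 0 passed the threshold, although Lcn2 was 2.84-fold and Serpina3n 2.20-fold above control. Fbxo32 differed by −0.28 (SE 0.39), Trim63 by −0.05 (SE 0.46), Mstn by 0.12 (SE 0.32), Igf1 by 0.05 (SE 0.21), Pdk4 by −0.43 (SE 0.35), Cdkn1a by 0.38 (SE 0.57), Serpina3n by 1.14 (SE 0.64) and Lcn2 by 1.504 (SE 0.96), each at an edgeR adjusted p of 1.00 and with overlapping groups. EdgeR called 0 of 12760 genes, with 413 at an unadjusted p under 0.05 and 561 (4.40%, 2.86% by chance) with non-overlapping groups. DESeq2 called 1 gene, with 494 at an unadjusted p under 0.05, and limma-trend on log2 FPKM called 0. In simulated data with these libraries' means and spread, 53.4% of genes changed 2-fold and 11.2% of genes changed 1.5-fold were recovered. Some list members differed when adjusted over the list alone: the erythroid genes Slc4a1 and Alas2 were higher in treated muscle, by 2.31 (SE 0.56) and 1.51 (SE 0.42), as were the neutrophil gene S100a9 at 3.66 (SE 0.80), and Osmr at 0.84 (SE 0.20) and Lrg1 at 0.67 (SE 0.17) of the interleukin-6 and STAT3 acute phase genes, with non-overlapping groups for each. Over all genes none of these passed. Camera called 9 of 34 lists, among them neutrophil markers (adjusted p = 8.25e-07; 0.134 with an estimated correlation), glucocorticoid genes, higher (adjusted p = 1.8e-05; 0.770 with an estimated correlation), and matrix genes, lower (adjusted p = 9.12e-06; 0.806 with an estimated correlation).

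The comparison of KPC with control heart asked whether the tumour changes the heart as well. Lcn2 (chromosome 2, 32384633 to 32388252) rose from 2.31 ± 0.591 to 61.1 ± 36.2 CPM, 26.4-fold (log2 fold change 4.72, SE 0.64, edgeR adjusted p = 0.00364), and Serpina3n from 9.39 ± 3.52 to 203 ± 121 CPM, 21.5-fold (4.43, SE 0.55, edgeR adjusted p = 0.00282). Cdkn1a rose from 19.9 ± 6.58 to 77.4 ± 38.3 CPM (1.96, SE 0.34, edgeR adjusted p = 0.0116). Fkbp5, a chaperone of the glucocorticoid receptor, rose by 2.89 (SE 0.33, edgeR adjusted p = 0.00245), Cebpd by 2.89 (SE 0.37), Tsc22d3, a glucocorticoid-induced transcription regulator, by 1.27 (SE 0.16), and Osmr, the oncostatin M receptor, by 1.83 (SE 0.22). Slc3a2, the shared chain of amino acid transporters, rose by 1.34 (SE 0.10, edgeR adjusted p = 0.000299). Akap5, an anchor of protein kinase A, fell to 1.74 ± 1.01 from 13.1 ± 2.90 CPM (−2.91, SE 0.34, edgeR adjusted p = 0.00245), Aplnr, the apelin receptor, by 2.69 on the log2 scale (SE 0.42) and the collagen gene Col15a1 by 1.95 (SE 0.30). The 4 KPC hearts lay entirely on one side of the 4 controls for every gene named so far, and each of these calls held when any 1 library was left out.

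Further genes changed in KPC heart, but their calls depended on single libraries. Myh7, the slow myosin heavy chain gene that fetal and stressed ventricles express (chromosome 14, 54970684 to 54994626), rose from 77.6 ± 10.1 to 3085 ± 3529 CPM (5.31, SE 1.05, edgeR adjusted p = 0.0182), at an adjusted p of 0.0595 to 0.0694 without control 1, 3 or 4. Nppb, a natriuretic peptide gene, fell by 1.51 on the log2 scale (SE 0.41, edgeR adjusted p = 0.0425), at 0.0685 to 0.118 without control 1, 3 or 4 or KPC 1, 2 or 3. Of 9 neutrophil markers 7 rose, with S100a8 at 5.43 (SE 1.01, edgeR adjusted p = 0.0153, and 0.0513 to 0.0586 without control 1, 3 or 4), and of 12 macrophage markers 7 rose, with Cd163 at 1.25 (SE 0.29, edgeR adjusted p = 0.0288, and 0.0569 to 0.0791 without control 1, 3 or 4 or KPC 2 or 3). Saa3, an acute phase protein, had 3 counts in the 4 control hearts and 12473 in the 4 KPC hearts, a ratio of 3752 after scaling (95% counting interval 1284 to 18197), and passed the test (edgeR adjusted p = 0.0179, and 0.0580 to 0.0681 without control 1, 3 or 4). Arginase gene Arg1 rose by 9.57 (SE 2.21, edgeR adjusted p = 0.0288) and by 6.71 without KPC 2, and osteopontin gene Spp1 by 7.50 (SE 1.75, edgeR adjusted p = 0.0297) and by 4.78 without KPC 2. Myh7 was at 4.27 without KPC 3, and without control 2 Arg1 was at 10.27 and S100a8 at 6.11. The log2 fold change of Saa3 was 11.51, at 12.41 without control 2 and 9.55 without KPC 2. Without any 1 control, KPC 2 or KPC 3 the adjusted p was 0.0507 to 0.0879 for Arg1 and 0.0562 to 0.0889 for Spp1. Fbxo32 (0.11, SE 0.28, edgeR adjusted p = 0.816), Trim63 (0.01, SE 0.23, edgeR adjusted p = 0.980), Mstn (−0.42, adjusted p = 0.695), Igf1 (−0.03, adjusted p = 0.962), Pdk4 (0.91, SE 0.36, adjusted p = 0.114), Nppa (−2.54, SE 1.12, adjusted p = 0.148) and Myh6 (−0.52, SE 0.30, adjusted p = 0.256) did not pass in heart by edgeR with all libraries. Myh6 passed without KPC 4 (−0.88, adjusted p = 0.0208), and Pdk4 passed with DESeq2 (0.91, DESeq2 adjusted p = 0.0458).

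EdgeR called 1293 of 13846 genes (9.34%), 686 higher and 607 lower in KPC heart, and 401 and 173 of them by at least 2-fold. The groups did not overlap for 1993 genes (14.4%, 2.86% by chance). Glucocorticoid-responsive genes rose in 10 of 18 cases (16 adjusted over the list alone; camera adjusted p = 2.47e-18, or 0.132 with an estimated correlation), interleukin-6 genes in 13 of 18 (16; 2.48e-17, or 0.305) and ribosomal protein genes in 28 of 45 (42; 2.47e-18, or 0.642). Macrophage and neutrophil markers had 12 and 7 calls adjusted over the list alone, at camera adjusted p = 8.87e-07 and 2e-07, or 0.642 and 0.537 with an estimated correlation. None of 31 proteasome subunits passed in heart by edgeR (list median 0.06, camera adjusted p = 0.429). Leaving out 1 library moved the count to 208 without control 1, 529 without control 2, 104 without control 3, 186 without control 4, 405 without KPC 2, 268 without KPC 3 and 3554 without KPC 4, and 50 of the 65 named calls were lost in at least 1 such fit. DESeq2 called 2499 genes and a fit of these 2 groups alone 229. With the atrial score (below) as a covariate edgeR called 648, and with only the 5 libraries low in atrial transcripts it called 0, with 1733 at an unadjusted p under 0.05, so that all 65 named calls were lost. Library totals alone, with the median of all genes at 0.17 instead of 0.02, gave 1698, of which 1368 were higher and 330 lower.

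The comparison of KPC+GnP with KPC heart asked whether treatment changes the heart in mice with the tumour. Lcn2 fell to 4.79 ± 1.82 CPM, 12.8-fold below KPC heart (−3.68, SE 0.60, edgeR adjusted p = 0.0244), Serpina3n fell to 27.01 ± 7.34 CPM, 7.52-fold below it (−2.91, SE 0.51, edgeR adjusted p = 0.0312), and Mt2 fell by 3.02 on the log2 scale (SE 0.57, edgeR adjusted p = 0.0328). Higher were Dio2, which activates thyroid hormone, at 5.01 (SE 0.73, edgeR adjusted p = 0.0223), Pnpla3, a lipid droplet enzyme, at 4.72 (SE 0.65, edgeR adjusted p = 0.0223), and Hydin, a cilium gene, at 5.97 (SE 0.95, edgeR adjusted p = 0.0223). For these 6 genes the groups did not overlap. Of 12 adipocyte markers 3 rose (5 adjusted over the list alone; camera adjusted p = 6.61e-06, or 0.677 with an estimated correlation), among them Plin1, which coats lipid droplets, at 5.82 (SE 1.28, edgeR adjusted p = 0.0476), and Ucp1, the brown fat uncoupling protein, at 9.39 (SE 1.87, edgeR adjusted p = 0.0488), with overlapping groups. Of 8 atrial cardiomyocyte markers 1 rose, Tbx5 at 1.86 (SE 0.41, edgeR adjusted p = 0.0462), while 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000103, or 0.677 with an estimated correlation). Myh7 at −4.32 (SE 1.00, edgeR adjusted p = 0.0517), Cdkn1a at −1.38 (SE 0.33, 0.0563), Pdk4 at −1.50 (SE 0.36, 0.0563), Nppa at 5.23 (SE 1.26, 0.0563) and Nppb at 1.55 (SE 0.41, 0.0713) did not pass, nor did Fbxo32 (−0.58, 0.263), Trim63 (−0.49, 0.255), Mstn (1.70, 0.157), Igf1 (0.47, 0.435) or Myh6 (0.28, 0.634). Leaving out 1 library changed calls both ways. The edgeR adjusted p reached 0.108 for Lcn2, 0.109 for Serpina3n, 0.124 for Mt2, 0.0861 for Dio2 and Pnpla3, 0.0942 for Hydin, 0.143 for Plin1 (7.86 without KPC 2), 0.142 for Ucp1 (14.83 without KPC 1) and 0.145 for Tbx5. Ucp1 was at 0 CPM in KPC hearts 2 to 4, so its value of 14.83 rests on the floor. In KPC+GnP hearts 1 to 3 Dio2 was at 5.56 to 6.34 log2 CPM and Ucp1 at 7.82 to 8.58. Heart 4 of that group had Dio2 at 1.70 and Ucp1 at −3.00. Brown fat in the samples as a source of the higher genes was not tested. The edgeR adjusted p fell under the threshold for Myh7 without KPC 1, KPC 4 or KPC+GnP 4 (0.0229 to 0.0399), Cdkn1a and Pdk4 without KPC 1 or KPC 4 (0.0229 to 0.0475), Nppa without KPC 1 or KPC+GnP 3 (0.0332 to 0.0468) and Nppb without KPC+GnP 3 (0.0305). With DESeq2 these 5 genes passed at the same threshold. Nppa is also 1 of the 8 atrial cardiomyocyte markers. Its change with treatment was therefore not separated from the share of atrial tissue in the samples.

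Atrial and fat transcripts differed between heart libraries within the groups. The atrial score, the mean log2 CPM of Myl7, Myl4, Sln, Bmp10 and Kcna5, was 3.63 ± 4.05 (SD, n = 4) in controls, 1.77 ± 2.69 in KPC and 8.07 ± 1.31 in KPC+GnP hearts. The adipocyte score, that of Adipoq, Plin1, Cidec and Cfd, was −0.63 ± 1.95, 0.88 ± 3.70 and 5.95 ± 3.23. Myl7, an atrial myosin light chain gene (chromosome 11, 5896637 to 5898782), ranged from −0.35 to 8.90 log2 CPM within the control hearts alone. Nppa was at 1778 and 2113 CPM in control hearts 2 and 4, where Myl7 was at 455 and 476 CPM. In control hearts 1 and 3 Nppa was at 115 and 156 CPM and Myl7 at 0.659 and 1.09 CPM. Ucp1 was at 7.82 to 8.58 log2 CPM in KPC+GnP hearts 1 to 3 and at −3.00 in heart 4.

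**Figure D3:**
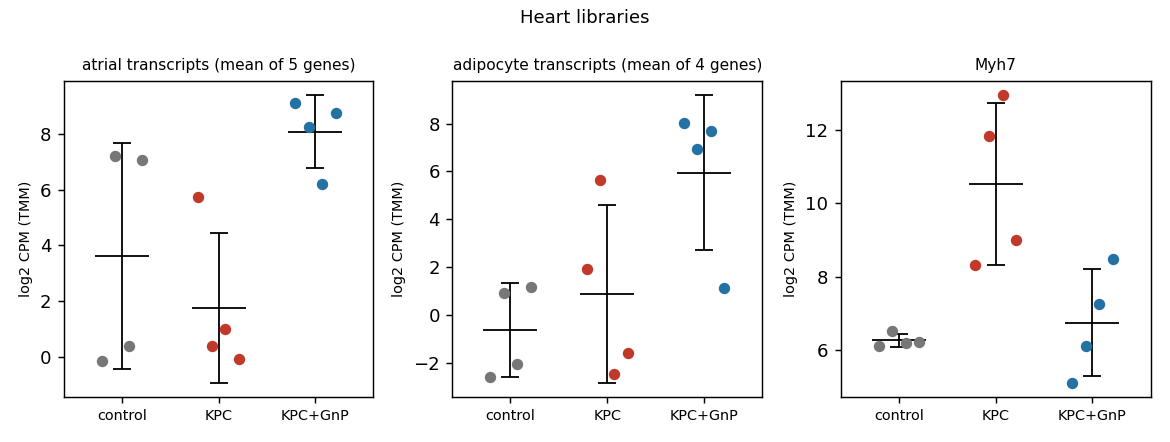
Atrial score, adipocyte score and Myh7 in each heart library, in log2 CPM, with the mean and SD of the 4 libraries of each group. Myh7 was above all 4 control hearts in all 4 KPC hearts, and the atrial score was above 6 in all 4 KPC+GnP hearts but spread from low to high within the control hearts.

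EdgeR called 214 of 13846 genes in KPC+GnP against KPC heart, 157 higher and 57 lower, with 2886 at an unadjusted p under 0.05, and the groups did not overlap for 1122 (8.10%, 2.86% by chance). Of the genes higher in KPC than in control heart, 45 were lower with treatment, where 2.82 are expected of independent lists, and 37 of the lower ones were higher, where 6.88 are expected. The covariance of the 2 comparisons across genes was −0.31 (r = −0.544), against −0.0649 in simulated unchanged groups and −0.145 with separate pairs of KPC hearts, ranging from −0.272 to 0.0838 over the 6 splits, so that the opposite direction was not seen in every split. Each of the 28 named calls was lost without KPC 2, KPC 3 or KPC+GnP 1, and the count was 1 without KPC 2, 0 without KPC 3, 1192 without KPC 4, 1 without KPC+GnP 1, 9 without KPC+GnP 2 and 420 without KPC+GnP 3. The balance between directions changed as well, with 576 higher and 616 lower without KPC 4. DESeq2 called 1136 genes (613 higher, 523 lower), a fit of these 2 groups alone 3, limma-trend on log2 FPKM 88, and with the atrial score as a covariate edgeR called 0, with 938 at an unadjusted p under 0.05, and with the adipocyte score 1337 (427 higher, 910 lower).

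The comparison of KPC+GnP with control heart asked what remains different in treated mice with the tumour. Akap5 fell to 1.84 ± 0.309 CPM (−2.82, SE 0.34, edgeR adjusted p = 0.00994) and Slc3a2 rose by 0.89 (SE 0.10, edgeR adjusted p = 0.00994), and both were at an adjusted p of 0.0507 to 0.0514 without control 1 or 3. Nos2, an inducible nitric oxide synthase gene, fell by 1.77 on the log2 scale (SE 0.27, edgeR adjusted p = 0.0224). Tsc22d3 rose by 1.07 (SE 0.16, edgeR adjusted p = 0.0196), Fkbp5 by 1.72 (SE 0.32, edgeR adjusted p = 0.0337) and Osmr by 1.17 (SE 0.21, edgeR adjusted p = 0.0337). Plin1 rose to 81.3 ± 60.5 from 0.402 ± 0.350 CPM (7.55, SE 1.46, edgeR adjusted p = 0.0355), and 4 of 12 adipocyte markers passed (11 adjusted over the list alone; camera adjusted p = 1.15e-07, or 0.431 with an estimated correlation). The groups did not overlap for any of these named genes. The edgeR adjusted p was 0.0627 to 0.104 for Nos2 without control 1, 3 or 4 or KPC+GnP 1 or 2, 0.0576 to 0.104 for Tsc22d3 without control 1, 2 or 3 or KPC+GnP 1 or 2, and up to 0.124 for Fkbp5, 0.123 for Osmr and 0.132 for Plin1 without any 1 control or KPC+GnP 1, 2 or 3. Serpina3n (1.51, SE 0.50, edgeR adjusted p = 0.134), Lcn2 (1.04, SE 0.61, 0.362), Cdkn1a (0.58, 0.345), Myh7 (1.00, SE 0.89, 0.555), Nppa (2.69, SE 1.12, 0.215), Nppb (0.04, 0.966), Myh6 (−0.24, 0.681), Fbxo32 (−0.48, 0.365), Trim63 (−0.48, 0.274), Mstn (1.28, 0.266), Igf1 (0.44, 0.467) and Pdk4 (−0.60, 0.366) did not pass, although Serpina3n did with DESeq2 (DESeq2 adjusted p = 0.0227) and in a fit of these 2 groups alone (edgeR adjusted p = 0.0241). EdgeR called 170 of 13846 genes, 113 higher and 57 lower, with 2753 at an unadjusted p under 0.05 and 2199 (15.9%, 2.86% by chance) with non-overlapping groups. Of these, 33 were also higher and 43 also lower in KPC than in control heart, where 5.60 and 2.499 are expected of independent lists. The covariance was 0.33 (r = 0.566), against 0.0650 in simulated unchanged groups with these shared controls and 0.314 (0.235 to 0.382 over 6 splits) with separate pairs of controls. The count was 1 without control 1, 17 without control 2, 1 without control 3, 14 without control 4, 9 without KPC+GnP 1, 7 without KPC+GnP 2, 49 without KPC+GnP 3 and 340 without KPC+GnP 4. DESeq2 called 1056 genes, a fit of these 2 groups alone 918, limma-trend on log2 FPKM 86, and edgeR called 1 with the atrial score and 2 with the adipocyte score as a covariate. Library totals alone, with the median of all genes at 0.17 instead of 0.01, gave 374, of which 328 were higher and 46 lower.

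Whether the tumour changes muscle and heart differently was asked with the difference between the effects in both tissues. Trim63 rose by 3.82 more on the log2 scale in muscle than in heart (SE 0.56, edgeR adjusted p = 0.000580), with log2 fold changes of 3.92 and 0.01. Arhgap26, a GTPase-activating protein gene, differed by 3.75 (SE 0.56, edgeR adjusted p = 0.000589), Kcnv2, a silent potassium channel subunit, by 4.24 (SE 0.78), and Zim1, an imprinted zinc finger gene, by 3.98 (SE 0.67). Myh7 went the other way, with a difference of −5.56 (SE 1.24, edgeR adjusted p = 0.00398), from −0.19 in muscle and 5.31 in heart. The complement gene Cfb differed by −5.23 (SE 1.06, edgeR adjusted p = 0.00252) and the pattern recognition gene Ptx3 by −5.80 (SE 1.14, edgeR adjusted p = 0.00215). For the difference in response to treatment, Myh7 was at 5.17 (SE 1.23, edgeR adjusted p = 0.00575), with 0.81 in muscle and −4.32 in heart, and Lrrc52, a channel subunit gene, at 4.03 (SE 0.67, edgeR adjusted p = 0.000778), while Plin1 was at −6.18 (edgeR adjusted p = 0.00624), with −0.39 in muscle and 5.82 in heart. Plin1 belongs to the adipocyte score, which differed between the heart libraries. Its response to treatment was not separated from the fat in the heart samples. Among lists, 29 of 31 proteasome subunits had a more positive effect of the tumour in muscle than in heart (30 adjusted over the list alone), and 18 of 24 matrix genes (21) and 16 of 24 interferon genes (20) a more negative one. Leaving out 1 library moved several of the differences. In response to the tumour, Cfb was at −4.50 without heart KPC 1, Myh7 at −4.51 without heart KPC 3, and Ptx3 at −7.01 without muscle KPC 1 and −4.99 without heart KPC 2. In response to treatment, Myh7 was at 4.12 without heart KPC 3, 4.44 without muscle KPC+GnP 1 and 6.01 without heart KPC+GnP 4, and Plin1 at −8.22 without heart KPC 2 and −6.80 without muscle KPC+GnP 3.

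**Figure D4:**
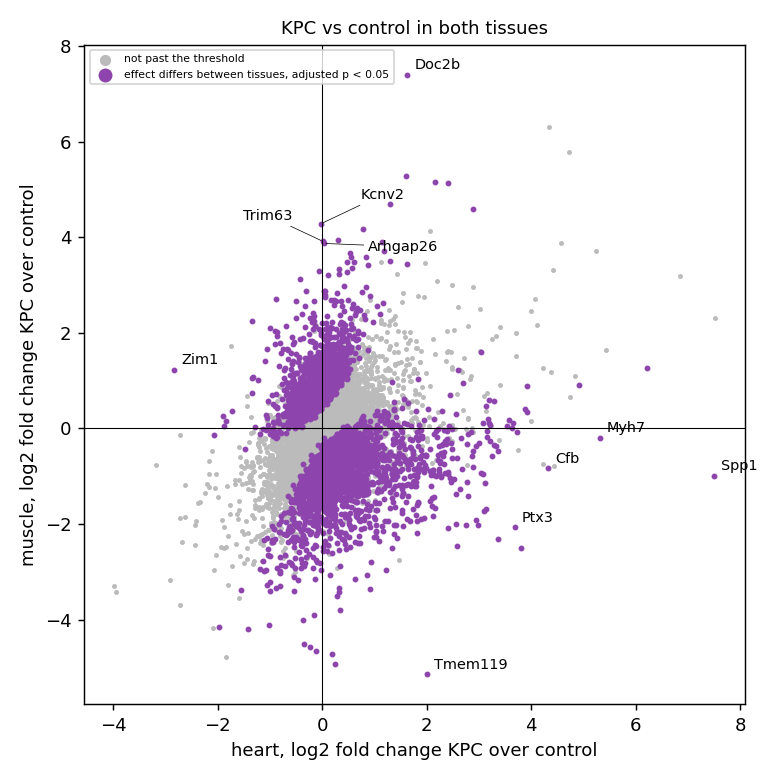
Log2 fold change of each gene for KPC vs control in heart (horizontal) and in muscle (vertical), with the genes whose effect differed between the tissues by edgeR coloured. Trim63 rose in muscle alone and Myh7 in heart alone.

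In all, 3747 of 14509 genes differed between the tissues in their response to the tumour by edgeR, 1800 more positive and 1947 more negative in muscle, and in their response to treatment 3725 did, 1813 and 1912. For the tumour the balance of directions turned with RLE size factors (2122 more positive, 1786 more negative) and with DESeq2 (2364 and 2127). For treatment it kept its side, at 1785 and 1983 with RLE and 2142 and 2246 with DESeq2. With the animals as a block, using only the 8 animals with both tissues, 1 and 25 genes passed, and with these libraries and no block 127 and 129. Every gene named for a difference lost its call under the block. For the tumour the 1 gene that passed was Foxo1, so no member of the proteasome, matrix or interferon lists passed there. Without the block these libraries already lost 6 and 8 of the 10 calls named per comparison. A voom fit of all libraries with the animal as a random block called 3188 and 3205. It lost 4 and 5 of the 10 named calls, as did voom without the block. Without muscle KPC 1 the edgeR counts were 5804 and 5694. Across 12390 genes tested in both tissues the log2 fold changes had r = 0.220 for KPC vs control and 0.157 for KPC+GnP vs KPC. Of the genes changed by the tumour in both tissues, 266 rose and 298 fell in both, where 167 and 122 are expected of independent lists, and 51 rose in muscle and fell in heart while 41 did the opposite, where 157 and 130 are expected.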

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

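The tests that weigh explanations in this part were all chosen after the results were seen; the test for a library standing apart and the test of the difference between tissues were set beforehand. In each group of 4 libraries, the gap between the highest or lowest library and its neighbour was divided by the range of the group, and a quotient above Dixon's 95% critical value for 4 libraries marked a library as standing apart. This held for 29 of 267 groups tested, where chance marks about 1 in 20 groups, or 13.4.

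Muscle KPC library 1 stood apart for 8 genes. It is the library of animal 141, whose count column has a name that differs by a final digit from the sample's title, and whether it is a repeat or a replacement was not tested. Its log2 CPM of Ddit4 was 5.51 against 8.14 to 8.20 in the other KPC libraries (quotient 0.978), of Fbxo32 10.44 against 12.69 to 12.89 (0.917), of Cebpd 4.99 against 7.44 to 7.76 (0.884) and of Trim63 9.04 against 11.88 to 12.39 (0.848). It was higher than the others for Fam167a (1.00), Kera (0.865), Chad (0.846) and Nmrk2 (0.836). On an axis from the control mean (0) to the mean of the other KPC libraries (1), over the genes changed in muscle, the library lay at 0.279, while controls left out in turn lay between −0.0472 and 0.0974 (SD 0.0607) and KPC libraries reached 1.16. A sham mouse under a wrong label would lie within the controls, which 0.279 argues against, and low depth is argued against by a total of 26827981 counts, within the 26031716 to 27382432 of the KPC libraries. The animal may have responded less to the tumour: its heart library, KPC heart 4, lay at 0.201 on the same axis in heart, the lowest KPC heart and within the controls' −0.0334 to 0.270. The other KPC hearts themselves lay between 0.592 and 1.34, and the SD with KPC heart 4 included was 0.471. A lesser response in both tissues therefore cannot be told apart from ordinary variation between hearts. Without this library, Fbxo32 in KPC vs control muscle was at 3.52 (SE 0.21) and Trim63 at 4.26 (SE 0.20), while Kera moved from −4.32 to −7.81 and Fam167a from −4.73 to −8.56. In KPC+GnP vs KPC muscle Kera moved from 4.19 to 7.67, Chad from 4.03 to 5.85 and Nmrk2 from 3.63 to 6.54.

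Heart KPC+GnP library 4 stood apart 6 times: for the adipocyte score, at 1.15 against 6.92 to 8.01 (quotient 0.841), for genes detected, at 14370 against 14432 to 14444 (0.838), and for Cx3cr1 (0.870), Prkar2b (0.864), Plin1 (0.860) and Dio2 (0.832). The libraries in this group thus differed in fat transcripts, and the atrial score also differed between groups, at 8.07 ± 1.31 in KPC+GnP and 1.77 ± 2.69 in KPC hearts. In heart, the 157 genes higher in KPC+GnP than in KPC mice had a median log2 fold change of 2.02 (median SE 0.380) and the 57 lower one of −0.99 (0.200). With the adipocyte score as a covariate the medians were 1.76 (0.466) and −0.85 (0.215), and 114 and 46 of these genes passed the threshold. That argues against fat as measured by this score as the whole cause. The score does not follow Ucp1, however: KPC heart 2 scored 5.64 with Ucp1 at −3.00 log2 CPM. KPC+GnP hearts 1 to 3 scored 6.92 to 8.01 with Ucp1 at 7.82 to 8.58. Brown fat as a source of the higher genes was therefore not tested. With the atrial score as a covariate the medians were 1.503 (0.536) and −0.80 (0.257) with 0 genes of either set past the threshold, as the standard errors grew while the medians shrank, so an effect of treatment and a larger share of atrial tissue in the samples cannot be told apart for these genes, because the score was at least 6.18 in the KPC+GnP and at most 5.74 in the KPC hearts.

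The count of 0 genes between KPC+GnP and control muscle was weighed as well. If the spread of the KPC libraries, shared in the fit, hid changes, a fit of only the 2 groups could call genes. It called 0. However, 1053 of 12610 genes had an unadjusted p under 0.05 in that fit, against 413 of 12760 with all 3 groups. The rise goes with hidden changes, and with 4 libraries per group a count of 0 cannot exclude them, so this explanation stays open. On the axis from control to KPC muscle, the highest KPC+GnP library lay at 0.0807 and the lowest at 0.000576, within the controls' −0.0472 to 0.0974, which is in line with treated muscle at the control level on this axis, although a change off this axis is not covered by the test. Whether the drugs act on muscle directly or through the tumour was not tested.

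Further libraries stood apart for single genes, for which no explanation was tested. In muscle these were control 1 for Cebpd (0.993), control 2 for Doc2b (0.888), control 3 for Fam167a (0.837) and Kera (0.884), KPC+GnP 1 for C1qtnf3 (0.863), and KPC+GnP 2 for Mfap4 (0.929), Mt1 (0.885) and Mt2 (0.960). In heart they were control 4 for Lep (1.00), KPC 2 for Prdm1 (0.841) and Sfrp5 (0.841), KPC 4 for Apol11b (0.948) and Lcn2, at 2.93 against 6.16 to 6.40 log2 CPM (0.929), KPC+GnP 1 for Apol11b (0.926) and KPC+GnP 3 for Zim1 (0.894). Heart KPC 4 is the heart library of animal 141, whose response in both tissues was weighed above over the changed genes, not for these 2.

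The effect of the tumour differed between muscle and heart for 3747 genes and that of the treatment for 3725, by the edgeR test of the difference, in a fit without the animals as a block. For KPC vs control, the differences (muscle minus heart, log2) were 5.72 for Doc2b, 4.24 for Kcnv2, 3.98 for Zim1, 3.82 for Trim63, 3.75 for Arhgap26, −5.23 for Cfb, −5.56 for Myh7, −5.80 for Ptx3, −7.22 for Tmem119 and −8.55 for Spp1. In response to treatment they were 6.41 for Spp1, 5.17 for Myh7, 4.71 for Msr1, 4.45 for Ptx3, 4.03 for Lrrc52, −5.62 for Cidec, −6.11 for Myl4, −6.18 for Plin1, −7.25 for Sln and −7.32 for Pck1. Myl4 and Sln belong to the atrial score and Cidec and Plin1 to the adipocyte score, and both scores differed between the heart libraries. For these genes a response to treatment was not separated from the make-up of the heart samples. Of the genes named for treatment, only Plin1 passed in heart alone (edgeR adjusted p = 0.0476). In the first comparison, leaving out heart KPC 2 moved Spp1 to −5.82, Tmem119 to −6.61 and Ptx3 to −4.99, heart KPC 1 Cfb to −4.50, heart KPC 3 Myh7 to −4.51, muscle KPC 1 Ptx3 to −7.01, muscle KPC 2 Doc2b to 4.51 and muscle control 3 Tmem119 to −6.62. In the second, leaving out heart KPC 2 moved Spp1 to 3.69, Msr1 to 3.02, Ptx3 to 3.63, Plin1 to −8.22, Cidec to −9.37 and Pck1 to −11.45, and leaving out heart KPC 1 moved Myl4 to −10.69 and Sln to −14.45. The KPC hearts left in that fit had Sln at 0 to 0.396 CPM, so its value rests on the floor. Further shifts in the second were Ptx3 to 5.66 without muscle KPC 1, Pck1 to −6.51 without muscle KPC 3, Myh7 to 4.12 without heart KPC 3, 4.44 without muscle KPC+GnP 1 and 6.01 without heart KPC+GnP 4, Msr1 to 3.54 without muscle KPC+GnP 2, Plin1 to −6.80 and Pck1 to −7.95 without muscle KPC+GnP 3, and Spp1 to 8.01 without heart KPC+GnP 3. Myl4 (adjusted p = 0.0329) lost its call in 7 of 16 such fits (0.0504 to 0.0605): without muscle KPC 3, any 1 muscle KPC+GnP library, heart KPC 3 or heart KPC+GnP 1.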

How the results depend on the processing

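Library totals alone, the covariates, the fits of only some heart libraries, and the fits between tissues of only 8 animals without the block or of voom without the block were chosen after seeing the data. The other settings were planned. In muscle, both comparisons with KPC kept their count within 1.5 times under every setting run: from 5423 to 6668 genes for KPC vs control and 5034 to 6757 for KPC+GnP vs KPC over the other planned settings. For KPC+GnP vs control, edgeR called 0 in every setting and DESeq2 called 1, Csf2rb (1.28, DESeq2 adjusted p = 0.0449). Of 113 named muscle calls in KPC vs control 99 held in all settings, and of 110 in KPC+GnP vs KPC 102 did. In heart, 0 of the 65, 28 and 22 named calls held in all settings. No named gene changed direction where it passed in either fit, and no list did with RLE size factors. Camera was also run with an estimated correlation, where the direction of a list was not compared. Genes that passed in neither did cross 0, as Igf1 in KPC vs control heart, at 0.13 without KPC 4.

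For KPC vs control heart the count was 2499 with DESeq2, 229 with only the 2 groups in the fit, 648 with the atrial score as a covariate and 0 with only the 5 libraries with low atrial transcripts, where fewer libraries were fitted and 1733 genes had an unadjusted p under 0.05. For KPC+GnP vs KPC heart it was 1136 with DESeq2, 3 with only 2 groups (Hydin, Hspa1a and Nat8l), 88 with limma-trend on log2 FPKM, 0 with the atrial score (938 unadjusted), 1337 with the adipocyte score and 5 with only the libraries with atrial transcripts (Prg4, Serpina3n, Mt2, Lcn2 and Timp1), which leaves 1 KPC library, assumed to vary like the others. For KPC+GnP vs control heart it was 1056 with DESeq2, 918 with only 2 groups, 86 with limma-trend, 374 with library totals alone, 1 with the atrial score (Hspa1a), 2 with the adipocyte score (Tinagl1 and Hspa1a) and 12 with only the libraries with atrial transcripts. The cause was not tested. Genes named for counts of 5 or fewer were chosen after their values were seen.

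Between tissues, the animal as a replicate block, fitted on the 8 animals with both tissues, gave 1 gene (Foxo1, 2.55, edgeR adjusted p = 0.0128) for KPC vs control and 25 for KPC+GnP vs KPC, with 3244 and 2726 at an unadjusted p under 0.05. The same libraries without the block gave 127 and 129, so that fewer libraries account for part of the fall. All libraries in voom with the block as a random effect gave 3188 and 3205. The block changed no other call, since no other comparison holds 2 libraries of one animal.

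Leaving out 1 library gave 5137 to 7993 genes for KPC vs control muscle, 5169 to 8056 for KPC+GnP vs KPC muscle, 0 to 0 for KPC+GnP vs control muscle, 104 (without control 3) to 3554 (without KPC 4) for KPC vs control heart, 0 (without KPC 3) to 1192 (without KPC 4) for KPC+GnP vs KPC heart and 1 (without control 1) to 340 (without KPC+GnP 4) for KPC+GnP vs control heart. Between tissues it gave 2677 to 5804 and 2867 to 5694, both highest without muscle KPC 1. Separate pairs of KPC libraries changed the covariance of KPC vs control with KPC+GnP vs KPC from −0.734 to −0.691 in muscle and from −0.310 to −0.145 in heart, where the 6 splits gave −0.272 to 0.0838. In the simulated data, where few genes changed, most changes of 1.5-fold were not recovered with 4 libraries per group. That does not carry over to muscle comparisons with KPC, where 49.7% and 49.8% of genes passed. Most calls there were below 2-fold: of 6336 genes in KPC vs control muscle, 995 higher and 1373 lower reached it.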

Other observations

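The tests of other splits of the libraries in this part were planned in kind but written after the results were seen. Genes of 5 further lists changed in muscle, although camera called none of these lists for KPC vs control (adjusted p = 0.0724 to 0.965). Of 8 satellite cell and regeneration genes, Pax7, which marks muscle stem cells, fell in KPC muscle by 1.89 on the log2 scale (SE 0.27, edgeR adjusted p = 0.000428) and Myod1, a myogenic transcription factor, by 1.45 (SE 0.33, edgeR adjusted p = 0.00377), while Cdh15 rose by 1.00 (SE 0.15, edgeR adjusted p = 0.000546), and all 3 went the other way with treatment, Pax7 by 1.88 (SE 0.27). Of 17 circadian clock genes 5 rose and 4 fell (5 and 4 adjusted over the list alone, and 4 and 6 with library totals alone), with Cry2, a clock repressor, at 2.10 (SE 0.33, edgeR adjusted p = 0.000616), Nfil3 at 2.03 (SE 0.33, edgeR adjusted p = 0.000717) and Bhlhe41 at −1.59 (SE 0.26, edgeR adjusted p = 0.000730). Of 19 p53 target genes 12 rose and 2 fell, with Sesn1, which restrains mTORC1, at 3.47 (SE 0.50, edgeR adjusted p = 0.000428), but camera did not call the list (adjusted p = 0.0724). Atf4, the transcription factor of the amino acid response, rose by 1.25 (SE 0.17) while its target Ddit3 fell by 1.51 (SE 0.21, edgeR adjusted p = 0.000372). Of 16 tubulins and microtubule regulators, the proteins that paclitaxel acts on, 3 rose and 6 fell, with Tuba1a at −1.63 (SE 0.29, edgeR adjusted p = 0.000994) and Tubb4b at 1.05 (SE 0.20, edgeR adjusted p = 0.00151), and with treatment Tuba1a rose by 1.55 (SE 0.29) and Tubb4b fell by 1.17 (SE 0.20). All of these genes had non-overlapping groups.

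In KPC muscle Slc4a1, the red cell anion exchanger, rose by 2.71 (SE 0.54, edgeR adjusted p = 0.00188, and 3.48 without control 4) with non-overlapping groups, and in heart it rose by 4.07 (SE 0.89, edgeR adjusted p = 0.0243, and 0.0505 to 0.0802 in 5 of 8 fits without 1 library) with overlapping groups. In muscle S100a9, a neutrophil protein, rose by 3.72 (SE 0.79, edgeR adjusted p = 0.00253). Of 7 lymphocyte markers in heart 0 passed by edgeR, with a list median of 3.07 (camera adjusted p = 0.264). Of 16 cell cycle genes in muscle 2 rose and 3 fell (0 and 3 adjusted over the list alone), with the mitotic kinase gene Aurka at −1.78 (SE 0.35, edgeR adjusted p = 0.00166) and at 1.96 with treatment.

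Other splits of the same libraries into groups of 4 show how often chance gives as many genes. For KPC vs control muscle, 1 of 35 splits, the real one, gave as many as 6336, and the highest other gave 3487. For KPC+GnP vs KPC muscle this was 1 of 35 with 6357 and 3646, and for KPC+GnP vs control heart 1 of 35 with 170 and 0. In these 3 comparisons the real split gave the most genes. A share of 1 in 35 is the smallest these splits can give, so they cannot exclude chance. For KPC vs control heart, 2 of 35 splits reached 1293 and the highest other gave 1381, with controls 1, 3 and 4 and KPC 4 on one side. In heart, for KPC+GnP vs KPC, 2 of 35 reached 214 and the highest other gave 557, over 2 times the real count. That split had KPC 1 to 3 and KPC+GnP 3 on one side, and why it gave more genes was not tested. Chance cannot be excluded for these 2 heart counts either. For KPC+GnP vs control muscle the real count was 0 and the highest other 0, so that all 35 splits reach it whatever they give, and the test says nothing about chance. Between tissues, in the fit without the animals as a block, 2 of 100 splits drawn reached 3747 (highest other 4392) and 3 of 100 reached 3725 (highest other 4964). The real split is counted among them. These splits regrouped libraries within each tissue, so they stand for no effect in either tissue, not for an equal effect in both. Other splits gave more genes in both comparisons, so chance is not excluded for the counts of that fit. Chance was not tested for the fit with the animals as a block, where 1 and 25 genes passed and every gene named for a difference lost its call.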
